A study of Homo sapiens with 60 samples.

How the data were processed

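RNA sequencing was carried out on HT29 cells, an established human colorectal adenocarcinoma line, 24 h after treatment with ethanol extracts of medicinal plants. The 60 libraries used here fell into 25 groups by their labels. One group was the vehicle, dimethyl sulfoxide (DMSO), with 3 libraries. Paeoniae Radix, Cnidii Rhizoma, Rehmanniae Radix Preparata, Astragali Radix and Cinnamomi Cortex each had 3 doses with 3 libraries per dose. Angelicae Gigantis Radix had 3 doses with 2 libraries each, numbered 2 and 3. The formulas Sagunja-tang and Samul-tang had 3 doses with 1 library each. Other libraries of the experiment, including the kinase inhibitors wortmannin and LY294002, were not analysed here. The labels put the vehicle at 0.1% DMSO while the text on the series gives 2%, and no label gives the amount of solvent that came with an extract dose. The labels do not say that libraries of one group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

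The values were expected counts per gene, which the authors made with RSEM 1.3.3 after STAR 2.7.3a, Trim Galore 0.6.5 and FastQC 0.11.9 on the hg38 (GRCh38) human genome, per the submitters' processing notes. The labels' protocols name a directional MGI library kit and paired-end sequencing of 100 bp. The strand setting of the counting and the annotation release are not given in the sources used here. RSEM divides reads that match several genes by estimation, so members of near-identical families (AKR1C1, AKR1C2 and AKR1C3, HSPA1A and HSPA1B, HSPA6 and HSPA7, metallothioneins, CYP4F, UGT1A, RGPD5, EIF3CL, RN7SL1 and RN7SL2) are uncertain one by one, and so are overlapping, read-through and antisense genes. The deposited table had 60675 gene entries and 273 columns, of which 213 were not used because they belonged to no library mapped here. Of the values used, 8.78% were not whole. Expected counts were rounded to whole numbers, which changed no library total by more than 0.000184%. Gene names came from a supplied table of identifiers for 56558 entries and from GENCODE v29 for another 497, and 0.528% of counts lay in entries with no name. Coordinates are those of GENCODE v29 on GRCh38. A total of 25033 genes were at 0 in all 60 libraries. Levels are given as CPM, the count scaled to the library total, as mean ± SD over libraries.

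Gene tests used edgeR 4.0.16 in R 4.3.3, with trimmed-mean (TMM) scaling, filtering of low counts by group and the quasi-likelihood F test. A single model held the 54 replicated libraries in 19 groups, so that all groups shared an estimate of spread, and 17089 genes were tested. Standard errors (SE) were the log2 change divided by the square root of F. Adjusted p-values are Benjamini-Hochberg values, with a threshold of 0.05. The 26 comparisons were each dose against vehicle, the high against the low dose of each extract, Cnidii Rhizoma against Rehmanniae Radix Preparata and Astragali Radix against Cinnamomi Cortex, each pair at the high dose and sharing a code set in the labels. In each, 31 gene lists were tested with camera of limma 3.58.1, with the correlation between genes estimated from the data and adjustment over the 31 lists. The preset correlation of 0.01 was an alternative. Lists share some members, such as NQO1 in the AhR and NRF2 lists and SLC7A5 in the AhR and ATF4 lists. Each list is given with its members called over all genes tested and with the number called when adjusted over the list alone. Single-library formulas had no test. Their medians over gene sets were placed among 10000 random sets of the same size matched on mean level in 20 bins.

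The groups, comparisons, gene lists, alternative settings and the rule for naming genes were fixed before the data were examined. For a high dose against vehicle the rule took the 8 largest changes in each direction among genes called against vehicle, called in the same direction against the low dose, with non-overlapping libraries and at least 2 CPM in the higher group. Separation of 3 libraries from 3 occurs by chance in 10% of unchanged genes. It also took up to 4 called members of each called list and 13 genes given whatever the result (CYP1A1, HMOX1, NQO1, HSPA1A, ASNS, DDIT3, HMGCS1, TXNIP, MKI67, CDKN1A, KRT20, MUC2 and AXIN2). Other comparisons took the 4 largest in each direction, and the formulas the 6 largest at 5 CPM or more. A subset of these genes is described, with preference for those whose call held without any one library. Differences between single libraries are of log2 CPM with a prior count of 2. For a gene at 0 in a group, the fold is a lower bound from a floor of 3 counts over that group. Intervals and floors cover counting error only.

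The alternatives fixed at that point were size factors and the Wald test of DESeq2 1.42.0, no filter, the replicate number as a block, a fit of the 2 groups compared alone, the other low doses as reference and leaving out each library in turn. Scaling by library totals, offsets for GC content (lowess span 0.3) and a fit without the Astragali Radix high-dose libraries were added after the data had been seen. The test was checked on simulated counts with 50 genes changed at each size. For Cnidii Rhizoma high against vehicle it recovered 46% of 1.25-fold, 78% of 1.5-fold, 98% of 2-fold and 100% of 4-fold changes, with 7 false calls among 192. For Angelicae Gigantis Radix, with 2 libraries, it recovered 26% of 1.25-fold and 86% of 1.5-fold changes, with 2 false calls among 155. For Rehmanniae Radix Preparata high against low it recovered 36% and 76%, with 7 false calls among 162. The simulated groups all varied alike by construction, whereas the real Astragali Radix high-dose libraries varied far more than the others. The check therefore does not give the false calls or recovery under such unequal spread. Of 51 pairs of libraries from one group, none differed by as little as sampling noise (chi-square per gene 1.92 to 223, 0 pairs with p over 0.05), so each library counted as 1 sample. Results for some genes are not reported here.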

Results

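Gene expression was measured by RNA sequencing in HT29 cells 24 h after exposure to ethanol extracts of 6 medicinal plants, to 2 formulas or to the DMSO vehicle. The question was what each extract does to the transcriptome and at which dose. The high dose was 500 µg/mL, or the dose that lowered viability by about 20% where that was lower, and the medium and low doses were 100 and 20 µg/mL. Angelicae Gigantis Radix was used at 320, 64 and 12.8 µg/mL, so its doses are not matched to the others. Library totals were 17798492 to 31134188 counts, and 21247 to 24191 genes were detected per library. The mean correlation of a library with the others of its group was 0.944 to 0.9938. Levels are means ± SD over 3 libraries, or 2 for Angelicae Gigantis Radix, and gene p-values are adjusted p from edgeR throughout, those of lists adjusted p from camera.

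In the fit of all groups Astragali Radix and Cnidii Rhizoma changed the most genes between the low and the high dose. The counts for the other extracts were lower and depended strongly on the fit. Against the low dose, 6176 genes were higher and 5821 lower with Astragali Radix, 922 and 822 with Cnidii Rhizoma. Paeoniae Radix gave 146 and 157. Cinnamomi Cortex gave 8 and 40, Rehmanniae Radix Preparata 10 and 10, and Angelicae Gigantis Radix 9 and 2. AKR1B10, an aldo-keto reductase, rose with all 6 extracts, by log2 0.39 to 2.95. Scaling by library totals, in place of TMM, gave 116 higher and 189 lower for Paeoniae Radix, 7 and 4 for Angelicae Gigantis Radix, 650 and 1109 for Cnidii Rhizoma and 4059 and 8430 for Astragali Radix. In the last of these it moved the median of all genes by -0.36 on the log2 scale, so changes with the Astragali Radix high dose are relative to the TMM level. In a fit without the Astragali Radix high-dose libraries the totals against the low dose rose. They were 1589 for Paeoniae Radix, 191 for Angelicae Gigantis Radix, 3905 for Cnidii Rhizoma, 242 for Rehmanniae Radix Preparata and 964 for Cinnamomi Cortex. In fits of the 2 groups alone they were 911 for Paeoniae Radix, 3616 for Cnidii Rhizoma, 174 for Rehmanniae Radix Preparata, 373 for Cinnamomi Cortex and 6113 for Astragali Radix. Small totals in the fit of all groups therefore do not show that few genes changed.

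**Figure D1:**
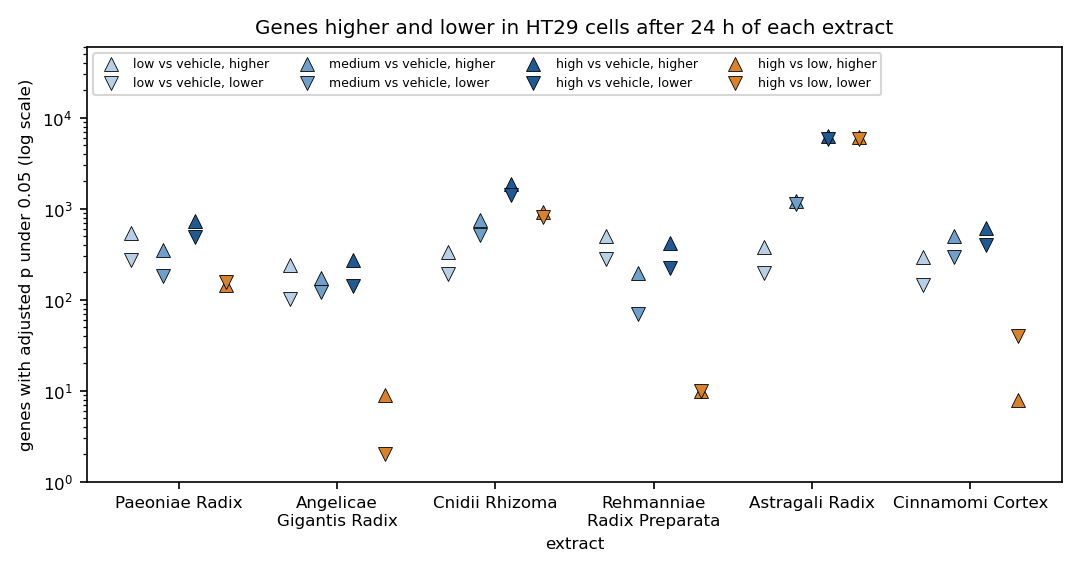
Number of genes called higher or lower at an adjusted p under 0.05 in each comparison with vehicle and between the high and low dose of each extract, on a log axis. Between the high and low doses the total runs from 11 with Angelicae Gigantis Radix to 11997 with Astragali Radix.

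Cnidii Rhizoma at 500 µg/mL raised genes of xenobiotic and redox metabolism. AKR1C2, a steroid and aldehyde reductase (ENSG00000151632, chromosome 10, 4987400 to 5018031, minus strand), went from 13.2 ± 0.564 CPM at the low dose to 314 ± 11.7 (log2 4.63 ± 0.12 SE, adjusted p = 9.9e-29). AKR1B10 (ENSG00000198074, chromosome 7, 134527592 to 134541408, plus strand) went from 120 ± 2.09 to 898 ± 40.1 (2.95 ± 0.06, adjusted p = 1.6e-34). HMOX1, which breaks down heme (ENSG00000100292, chromosome 22, 35380361 to 35394214, plus strand), went from 12.4 ± 0.368 to 72.9 ± 0.984 (2.61 ± 0.10, adjusted p = 1.1e-22). NQO1, a quinone reductase, went from 534 ± 9.47 to 1130 ± 31.3 CPM, and SLC7A11, the cystine importer, from 148 ± 7.86 to 502 ± 16.7. Of 28 targets of the oxidative stress regulator NRF2, 27 were higher and none lower (28 adjusted over the list alone, median log2 1.26, adjusted p = 1.7e-09). Against vehicle 27 were also higher (27 adjusted over the list alone, median 1.34, adjusted p = 5.2e-08). At the medium dose 23 were (26 adjusted over the list alone, median 0.47, adjusted p = 1.1e-04), with AKR1B10 at 234 ± 4.31 CPM against 91.6 ± 9.33 in vehicle. AKR1C1, AKR1C2 and AKR1C3 are near-identical and their split is uncertain. SLC38A4, an amino acid transporter, rose from 3.96 ± 0.488 to 46.5 ± 1.4 CPM (3.60 ± 0.14).

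The same dose of Cnidii Rhizoma raised genes of fatty acid handling, protein folding in the endoplasmic reticulum (ER) and amino acid supply. Of 18 PPAR and fatty acid oxidation genes, 13 were higher against the low dose (13 adjusted over the list alone, adjusted p = 1.7e-09). Among them were FABP1, a fatty acid binding protein (2.78 ± 0.366 to 12.5 ± 0.867 CPM), and PDK4, which restrains pyruvate oxidation (log2 1.76 ± 0.18). Of 18 ER chaperones, 17 were higher (17 adjusted over the list alone, median 0.70, adjusted p = 9e-05). HSPA5, the main ER chaperone, was at 770 ± 27.2 against 442 ± 6.81 CPM and DNAJB9 at 29.6 ± 2.42 against 12.3 ± 0.982. Of 26 ATF4 and amino acid response genes, 17 were higher (20 adjusted over the list alone, adjusted p = 4.9e-09), with asparagine synthetase ASNS at 108 ± 5.38 against 52.5 ± 1.51 CPM. AhR targets had 4 higher of 10 (4 adjusted over the list alone, adjusted p = 5.6e-07). PXR and CAR targets, which handle drugs, had 5 of 9 (5 adjusted over the list alone, adjusted p = 0.0021), with UGT1A1 by 0.86 ± 0.09 and CYP2B6 by 1.09 ± 0.17. The intestinal keratin KRT20 rose by 0.74 ± 0.14.

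Among genes that fell with Cnidii Rhizoma were SLC14A1, CLIC5 and the chemokine CXCL8. The urea transporter SLC14A1 was at 1.11 ± 0.266 CPM against 5.48 ± 0.293 at the low dose (log2 -2.25 ± 0.20, adjusted p = 1.4e-11). CLIC5, an intracellular channel family member, fell by 2.01 ± 0.15, and SYTL2, of vesicle trafficking, by 1.58 ± 0.20. The neutrophil-attracting chemokines CXCL8 and CXCL1 fell by 0.95 ± 0.11 (adjusted p = 2.6e-08) and 1.09 ± 0.26. Of 20 NF-kB targets and chemokines, 6 were lower (1 higher and 8 lower adjusted over the list alone, median -0.22, adjusted p = 0.0021). Likewise 1 of 26 mitosis genes was lower (1 adjusted over the list alone, median -0.18, adjusted p = 9.6e-04). Hypoxia genes went both ways, with 6 higher and 1 lower of 21 (9 and 2 adjusted over the list alone, adjusted p = 0.019). This call was lost without the Astragali Radix high-dose libraries (0.096, against 0.0035 at the lowest of its alternatives). Against vehicle 1851 genes were higher and 1403 lower. The same 9 lists were called in the same directions together with glycolysis (7 of 17 higher, 8 adjusted over the list alone, adjusted p = 0.036). Without vehicle library 3 the calls against vehicle of hypoxia (adjusted p = 0.066) and glycolysis (0.064) were lost. Without the Astragali Radix high-dose libraries so were those of hypoxia (0.16), glycolysis (0.07), AhR (0.056), NF-kB (0.12) and PXR and CAR targets (0.052). At the medium dose ATF4 genes (8 of 26, 10 adjusted over the list alone, adjusted p = 5.6e-04), PPAR genes (6 of 18, 9 adjusted over the list alone, adjusted p = 5.5e-05) and glycolysis (6 of 17, 8 adjusted over the list alone, adjusted p = 0.039) were higher too.

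Astragali Radix at 500 µg/mL raised heat shock, oxidative stress and unfolded protein genes and lowered those of mitosis. HSPA6, an inducible chaperone (ENSG00000173110, chromosome 1, 161524540 to 161526910, plus strand), was at 1490 ± 1470 CPM against 0.241 ± 0.0878 at the low dose (log2 12.95 ± 0.55, adjusted p = 3e-23). HSPA1A was at 2670 ± 1690 against 296 ± 17.3 (3.55 ± 0.20, adjusted p = 1.4e-19). Near-identical copies share reads with both. High-dose library 3 carried much of both: without it the change was 11.64 for HSPA6, Astragali Radix high vs low, and 2.82 for HSPA1A, Astragali Radix high vs low, where HSPA1A stood at 1860, 1530 and 4610 CPM in libraries 1, 2 and 3. The co-chaperone BAG3 rose from 51.3 ± 3.38 to 854 ± 285 CPM and HMOX1 from 11.1 ± 0.56 to 310 ± 75.6 (5.18 ± 0.11, adjusted p = 3.2e-33). The stress factor DDIT3 rose from 6.37 ± 0.621 to 95.9 ± 9.49, and the cell cycle inhibitor CDKN1A from 14.9 ± 1.15 to 262 ± 41.7 (4.50 ± 0.10). The proliferation antigen MKI67 went from 861 ± 47 to 157 ± 94 CPM (-2.12 ± 0.18, adjusted p = 2.3e-13) and the centromere motor CENPE from 68.8 ± 5.53 to 8.01 ± 4.98. The goblet cell genes MUC2, a secreted mucin, and ATOH1, its lineage regulator, fell by 2.74 ± 0.16 and 3.78 ± 0.20, but the list of 13 secretory lineage markers was not called (3 higher and 6 lower, the same adjusted over the list alone, adjusted p = 0.62). Mitochondrial transcripts took 1.3, 5.2 and 5.4% of counts in these libraries, against means of 6.6% at the low and 7.1% at the medium dose of this extract (9.2% in vehicle). They had TMM factors of 0.814 on average and a within-group correlation of 0.9539 on average. Pairs of these libraries differed by a chi-square per gene of 91.17, 194.37 and 223.31, against 13.74 at most in any other group. The SE and p-values at this dose come from the spread shared by all groups and understate its own. In a fit of the 2 groups alone, 6113 genes were called against the low dose in place of 11997.

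By lists, 17 of 18 heat shock genes were higher against the low dose with Astragali Radix and none lower (median log2 2.03, adjusted p = 2.3e-04). So were 26 of 28 NRF2 targets with 1 lower (1.28, 0.024), 22 of 26 ATF4 genes with 2 lower (1.13, 9.4e-05) and 18 of 18 ER chaperones (1.16, 0.041). All list counts against the low dose were the same adjusted over the list alone. Of 20 NF-kB genes 16 were higher and 2 lower (1.49, 4.3e-04), with the chemokine-inducing IL32 by 4.43 ± 0.28. Of 21 hypoxia genes 15 were higher and 2 lower (1.04, 0.0014), with NDRG1 from 16.1 ± 1.54 to 231 ± 22.6 CPM and the vasodilator ADM by 5.78 ± 0.18. MAPK output and immediate early genes had 16 higher and 5 lower of 23 (1.3, 0.032), with FOSL1 by 4.26 ± 0.11 and the phosphatase DUSP5 by 5.28 ± 0.13. Glycolysis had 12 higher and 2 lower of 17 (0.73, 0.045). Lysosome and autophagy had 20 and 1 of 22 (1.14, 0.045), with the autophagy receptor SQSTM1 from 402 ± 8.95 to 2220 ± 806 CPM. Replication-dependent histones had 12 of 12 higher (2.14, 0.041), of 34 on the list. The listed histones took only 0.008, 0.007 and 0.011% of counts in the high-dose libraries, against 0.003% at the low dose. Mitosis genes had 3 higher and 20 lower of 26 (-0.75, 2.3e-04), with ASPM by -2.52 ± 0.17. Against vehicle, with 6238 genes higher and 5840 lower, the same lists were called except histones (adjusted p = 5.2e-05 to 0.048). The call of ER chaperones was lost with the replicate number as a block (0.05). The calls of ER chaperones (0.099) and MAPK (0.11) were lost without high-dose library 2, those of glycolysis (0.054) and MAPK (0.054) without library 3 and that of lysosome (0.067) without library 1. Leaving out the high-dose library 2 ended the calls against the low dose of ER chaperones (adjusted p = 0.082), glycolysis (0.069), MAPK (0.069), lysosome (0.06) and histones (0.064). Leaving out library 3 ended that of glycolysis (0.085) and library 1 that of lysosome (0.07). Under library totals the splits were 4059 higher and 8430 lower against the low dose and 4536 and 7910 against vehicle.

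**Figure D2:**
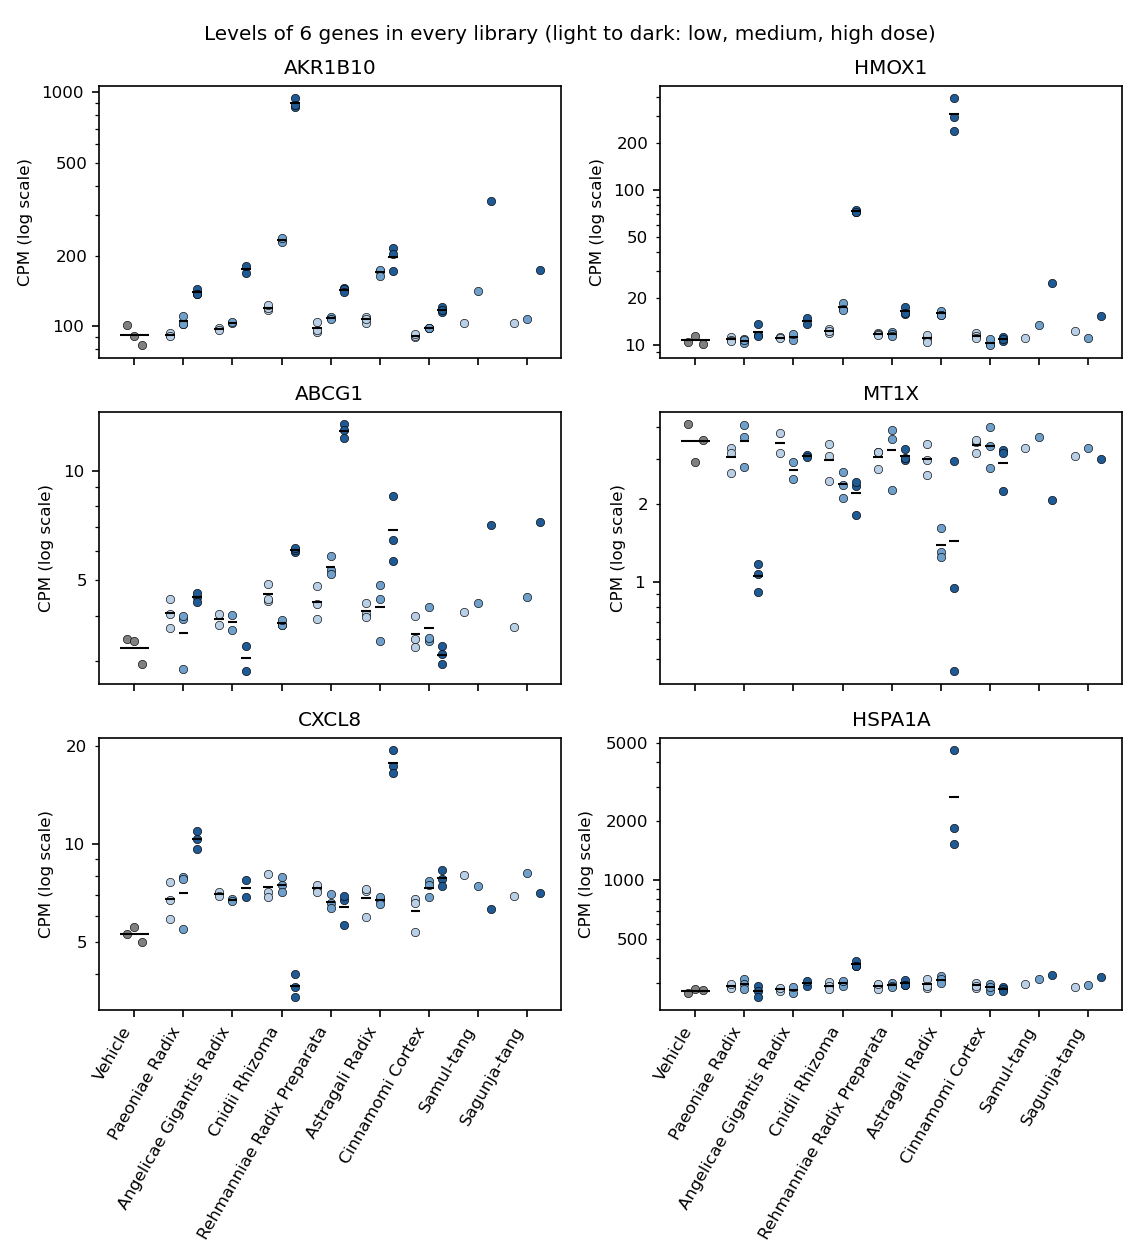
CPM per library (points, log axis) and group means (bars) of AKR1B10, HMOX1, ABCG1, MT1X, CXCL8 and HSPA1A in vehicle and at each dose of the 6 extracts. HMOX1 lies at 310 CPM on average with the Astragali Radix high dose and at 10.7 in vehicle, and MT1X at 1.05 with the Paeoniae Radix high dose and 3.52 in vehicle.

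At 100 µg/mL Astragali Radix raised AKR1C2 from 11.5 ± 1.74 CPM in vehicle to 37.5 ± 1.23 (log2 1.72 ± 0.12, adjusted p = 1.9e-13). NQO1 rose by 0.59, ACAT2, of sterol synthesis, by 0.6 ± 0.07 and the pseudokinase TRIB3 by 0.81 ± 0.08. NRF2 targets had 22 of 28 higher (23 adjusted over the list alone, median 0.38, adjusted p = 0.001), and cholesterol synthesis 16 of 23 (18 adjusted over the list alone, median 0.37, adjusted p = 0.0066). Glycolysis had 10 of 17 (11 adjusted over the list alone, adjusted p = 9.9e-04), ATF4 genes 8 of 26 (13 adjusted over the list alone, adjusted p = 9.9e-04) and PPAR genes 3 of 18 (5 adjusted over the list alone, adjusted p = 0.025). In all, 1225 genes were higher and 1123 lower. The total of 2348 was 1153 without vehicle library 3 and 1558 without library 2 of this dose. The low dose already differed from the same vehicle in 574 genes, and the medium dose was not tested against the low dose. Part of the total may therefore be a difference of the vehicle libraries.

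Paeoniae Radix at 500 µg/mL raised stress response and glycolytic genes and lowered metallothioneins and goblet cell genes. CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339, plus strand) was at 25.4 ± 2.05 CPM against 14.1 ± 0.828 at the low dose (log2 0.87 ± 0.09, adjusted p = 4.6e-08) and 13.7 ± 0.593 in vehicle. DUSP5 was at 7.88 ± 1.02 against 3.87 ± 0.161 (1.04 ± 0.13) and CHAC1, which degrades glutathione, at 5.42 ± 0.546 against 3.02 ± 0.0593. The glucose transporter SLC2A1 was at 676 ± 16.2 against 487 ± 7.18 (0.49 ± 0.04, adjusted p = 7.9e-10). CXCL8 rose by 0.64 ± 0.10. The metal-binding MT1X (ENSG00000187193, chromosome 16, 56682424 to 56684196, plus strand) went from 3.04 ± 0.346 to 1.05 ± 0.129 CPM (-1.52 ± 0.29, adjusted p = 0.0016). Against vehicle MT2A and MT1E fell by 1.38 ± 0.21 and 1.27 ± 0.28. MUC2 went from 19.2 ± 0.806 to 11.3 ± 0.181 CPM (-0.74 ± 0.12, adjusted p = 2.1e-04). ATOH1 went from 4.88 ± 0.577 to 2.67 ± 0.225, and FCGBP, a mucus protein, fell by 0.70 ± 0.12.

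Among the lists, ATF4 genes had 7 of 26 higher against the low dose of Paeoniae Radix (15 adjusted over the list alone, median log2 0.25, adjusted p = 1.4e-08), hypoxia 6 of 21 (9 adjusted over the list alone, 4.2e-08) and glycolysis 6 of 17 (13 adjusted over the list alone, 6.3e-06). NRF2 targets had 6 of 28 higher (11 adjusted over the list alone, 0.0026) and cholesterol synthesis 4 of 23 (6 adjusted over the list alone, 0.014). MAPK genes had 5 higher and 1 lower of 23 (8 and 1 adjusted over the list alone, 1.3e-04). NF-kB had 1 of 20 (1 adjusted over the list alone, 6.9e-04) and AhR targets 1 of 10 (4 adjusted over the list alone, 0.0013). The called AhR member was NQO1, which is also an NRF2 target. Metallothioneins had 2 of 7 lower (6 adjusted over the list alone, median -0.99, adjusted p = 0.0055) and secretory lineage markers 6 of 13 lower (6 adjusted over the list alone, adjusted p = 0.010). Against vehicle all of these but AhR were called in the same direction. Wnt and stem cell markers had 5 of 15 lower (6 adjusted over the list alone, adjusted p = 0.014), with the intestinal stem cell receptor LGR5 by -0.35 ± 0.06, and histones had 3 of 12 lower (4 adjusted over the list alone, adjusted p = 0.039). Neither the Wnt nor the histone list was called against the low dose. For them a difference of the vehicle libraries cannot be told apart from an effect of the dose. PXR and CAR targets (1 of 9 higher, 3 higher and 1 lower adjusted over the list alone, adjusted p = 0.037) and lung epithelium markers (0 of 3, 2 lower adjusted over the list alone, adjusted p = 0.037) were also called against the low dose. They were not in a fit with no filter (0.14 and 0.18, the highest of their alternatives, the lowest being 0.002 and 0.0066). Without the Astragali Radix high-dose libraries cholesterol synthesis against the low dose (0.051) and NF-kB against vehicle (0.059) were not called. Histones were not called without vehicle library 2 (0.11) or high-dose library 1 (0.065) or 2 (0.091). NF-kB against vehicle was lost without high-dose library 1 (0.063), and the call of PXR and CAR targets without high-dose library 1 (0.08) or low-dose library 2 (0.062) or 3 (0.092). The lung list was not called without high-dose library 1 (0.059) or 3 (0.11) or low-dose library 1 (0.057) or 2 (0.094).

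Against vehicle 727 genes were higher and 484 lower with the high dose of Paeoniae Radix, or 983 and 356 under library totals. The total of 1211 was 490 without vehicle library 3, 776 without high-dose library 1 and 685 without library 3. Against the low dose the total of 303 was 113, 184 and 183 without high-dose libraries 1, 2 and 3, and 194 and 135 without low-dose libraries 2 and 3.

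Rehmanniae Radix Preparata at 500 µg/mL raised the sterol exporter genes ABCG1 and ABCA1. ABCG1 (ENSG00000160179, chromosome 21, 42199689 to 42297244, plus strand), was at 12.9 ± 0.555 CPM against 4.35 ± 0.453 at the low dose (log2 1.58 ± 0.11, adjusted p = 5.9e-13) and 3.27 ± 0.284 in vehicle. ABCA1 was at 9.51 ± 0.877 CPM against 5.05 ± 0.728 in vehicle (0.86 ± 0.12, adjusted p = 1.9e-05), while MYLIP, a ubiquitin ligase, was at 21.4 ± 0.921 against 13.3 ± 0.907 (0.64 ± 0.13). TM7SF2, of sterol synthesis, went from 46.4 ± 2.28 to 33 ± 1.77 CPM between the low and high dose (-0.48 ± 0.07, adjusted p = 1e-04). AKR1B10 rose by 0.56 ± 0.05 against the low dose, and HMOX1 by 0.58 ± 0.11 and the cytokine GDF15 by 0.47 ± 0.05 against vehicle. Cholesterol synthesis genes were lower as a list against the low dose, with 1 of 23 called (15 adjusted over the list alone, median -0.23, adjusted p = 2.4e-04). NRF2 targets had 4 of 28 higher (20 adjusted over the list alone, median 0.24, adjusted p = 1.6e-05) and AhR targets 1 of 10 (4 adjusted over the list alone, adjusted p = 7.9e-07). The called AhR member was NQO1, which is in the NRF2 list too.

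Further lists passed with Rehmanniae Radix Preparata on few or no called members. Against the low dose these were mitosis (median log2 0.08, adjusted p = 0.012), heat shock (0.07, 0.033), MAPK (0.09, 0.036) and hepatocyte markers (3 measured, -0.53, 0.048), with 0 members called in each (1 MAPK gene higher and 0 in the others adjusted over the list alone). Leaving out high-dose library 1 ended the calls of heat shock (0.064), mitosis (0.064) and MAPK (0.064). Leaving out high-dose library 2 ended those of heat shock and MAPK (0.057 each), low-dose library 2 that of heat shock (0.087) and low-dose library 1 that of MAPK (0.091). The hepatocyte call was lost without high-dose library 1 (0.094) or 2 (0.066), low-dose library 1 (0.16) or 3 (0.055), or the Astragali Radix high-dose libraries (0.099), and with no filter (0.41) or with the replicate number as a block (0.05). Against vehicle, NRF2 targets had 11 of 28 higher (18 adjusted over the list alone, adjusted p = 0.023) and ATF4 genes 4 of 26 (4 adjusted over the list alone, 0.029). Wnt markers had 2 of 15 lower (1 higher and 7 lower adjusted over the list alone, 0.029) and hepatocyte markers 1 of 3 lower (2 adjusted over the list alone, 0.029, but 0.065 without vehicle library 2 and 0.10 without the Astragali Radix high-dose libraries). The Wnt list was not called against the low dose, so a difference of the vehicle libraries cannot be told apart. In all 424 genes were higher and 224 lower against vehicle, or 795 and 152 under library totals. The total of 648 was 363 and 278 without vehicle libraries 2 and 3, and 389 and 293 without high-dose libraries 1 and 2. The 20 genes called against the low dose became 33 with the replicate number as a block and 6 to 10 when any 1 of the 6 libraries was left out (9, 10 and 6 without high-dose libraries 1, 2 and 3, and 10, 7 and 8 without those of the low dose).

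Angelicae Gigantis Radix at 320 µg/mL raised AKR1B10 from 97.2 ± 1.77 CPM at 12.8 µg/mL to 175 ± 9.6 (log2 0.87 ± 0.06, adjusted p = 3.1e-12, n = 2 per group by edgeR). Against vehicle (n = 3), SLC38A4 (ENSG00000139209, chromosome 12, 46764761 to 46832408, minus strand) was at 6.77 ± 0.614 CPM against 2.63 ± 0.194 (1.32 ± 0.18). NQO1 was at 616 ± 22.7 against 447 ± 33.6 (0.42 ± 0.05), and the aldehyde dehydrogenases ALDH3A1 and ALDH3A2 rose by 0.58 ± 0.11 and 0.36 ± 0.05. NRF2 targets had 4 of 28 higher against the low dose (13 adjusted over the list alone, median 0.28, adjusted p = 3.4e-05) and 7 against vehicle (15 adjusted over the list alone, adjusted p = 0.015). AhR targets had 2 of 10 higher against the low dose (4 adjusted over the list alone, adjusted p = 5.8e-07), ALDH3A1 and NQO1, of which NQO1 is in the NRF2 list too, while CYP1A1 was not called (adjusted p = 1). For ALDH3A1, Angelicae Gigantis Radix high vs low, the call was lost without high-dose library 2 (0.14) or 3 (0.24) or low-dose library 2 (0.27) or 3 (0.32), and for NQO1, Angelicae Gigantis Radix high vs low, without high-dose library 3 (0.31) or low-dose library 2 (0.14) or 3 (0.32). The NQO1 call against the low dose was also lost with no filter (adjusted p = 0.72). PPAR genes had 3 of 18 higher against vehicle (4 adjusted over the list alone, adjusted p = 0.0031) and 0 against the low dose (median 0.11, adjusted p = 0.0037). Against vehicle, glycolysis had 2 of 17 higher (7 adjusted over the list alone, adjusted p = 0.021, but 0.10 without high-dose library 2) and ATF4 genes 2 of 26 (3 adjusted over the list alone, adjusted p = 0.015).

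Against the low dose of Angelicae Gigantis Radix, mitosis (median log2 0.10, adjusted p = 0.0037), heat shock (0.13, 0.034), glycolysis (0.11, 0.034) and, downward, interferon response (-0.20, 0.034) also passed with 0 members called (1 interferon gene lower and 0 in the others adjusted over the list alone). Heat shock was not called without high-dose library 2 (0.074) or 3 (0.11) or low-dose library 2 (0.11), nor glycolysis without high-dose library 2 (0.18) or low-dose library 2 (0.11) or 3 (0.057). Interferon response was not called without library 2 of the high (0.18) or low dose (0.21), or without the Astragali Radix high-dose libraries (0.051). Against vehicle 276 genes were higher and 140 lower, or 577 and 115 under library totals. The total of 416 was 200 and 183 without vehicle libraries 2 and 3 and 118 and 77 without high-dose libraries 2 and 3. The 11 genes called against the low dose became 2 and 3 without high-dose libraries 2 and 3 and 1 without either low-dose library, and AKR1B10 was called in each.

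Cinnamomi Cortex at 500 µg/mL lowered SLC6A20, an amino acid transporter (ENSG00000163817, chromosome 3, 45755450 to 45796535, minus strand), from 9.72 ± 0.355 CPM at the low dose to 5.62 ± 0.653 (log2 -0.77 ± 0.12, adjusted p = 0.00026). The adhesion receptor ADGRF1 rose from 32.8 ± 0.986 to 47.5 ± 2.79 CPM (0.55 ± 0.08) and AKR1B10 from 91.2 ± 1.23 to 118 ± 3.17 (0.39 ± 0.05, adjusted p = 4.1e-05). Against vehicle the replication factor MCM3 rose by 0.35 ± 0.05 and CREB3L1, a membrane-bound transcription factor, fell by 0.49 ± 0.06. Cholesterol synthesis had 2 of 23 lower against the low dose (3 adjusted over the list alone, adjusted p = 0.032) and secretory markers 0 of 13 (6 lower adjusted over the list alone, median -0.31, adjusted p = 0.015). AhR targets had 0 of 10 (4 higher adjusted over the list alone, adjusted p = 6.7e-04) and mitosis 0 of 26 (median 0.13, adjusted p = 2.5e-04). The cholesterol call was lost without high-dose library 2 (0.081) or 3 (0.082), low-dose library 1 (0.071) or 2 (0.06) or the Astragali Radix high-dose libraries (0.05). The secretory call was lost without high-dose library 2 (0.054) or with no filter (0.069). Against vehicle no list was called by camera with an estimated correlation, and 12 were with the preset one. In all 607 genes were higher and 397 lower against vehicle, or 1015 and 284 under library totals. The total of 1004 was 542 and 306 without vehicle libraries 2 and 3 and 655, 426 and 505 without high-dose libraries 1, 2 and 3. The 48 genes against the low dose became 8, 12 and 22 without high-dose libraries 1, 2 and 3 and 10, 21 and 13 without those of the low dose.

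**Figure D3:**
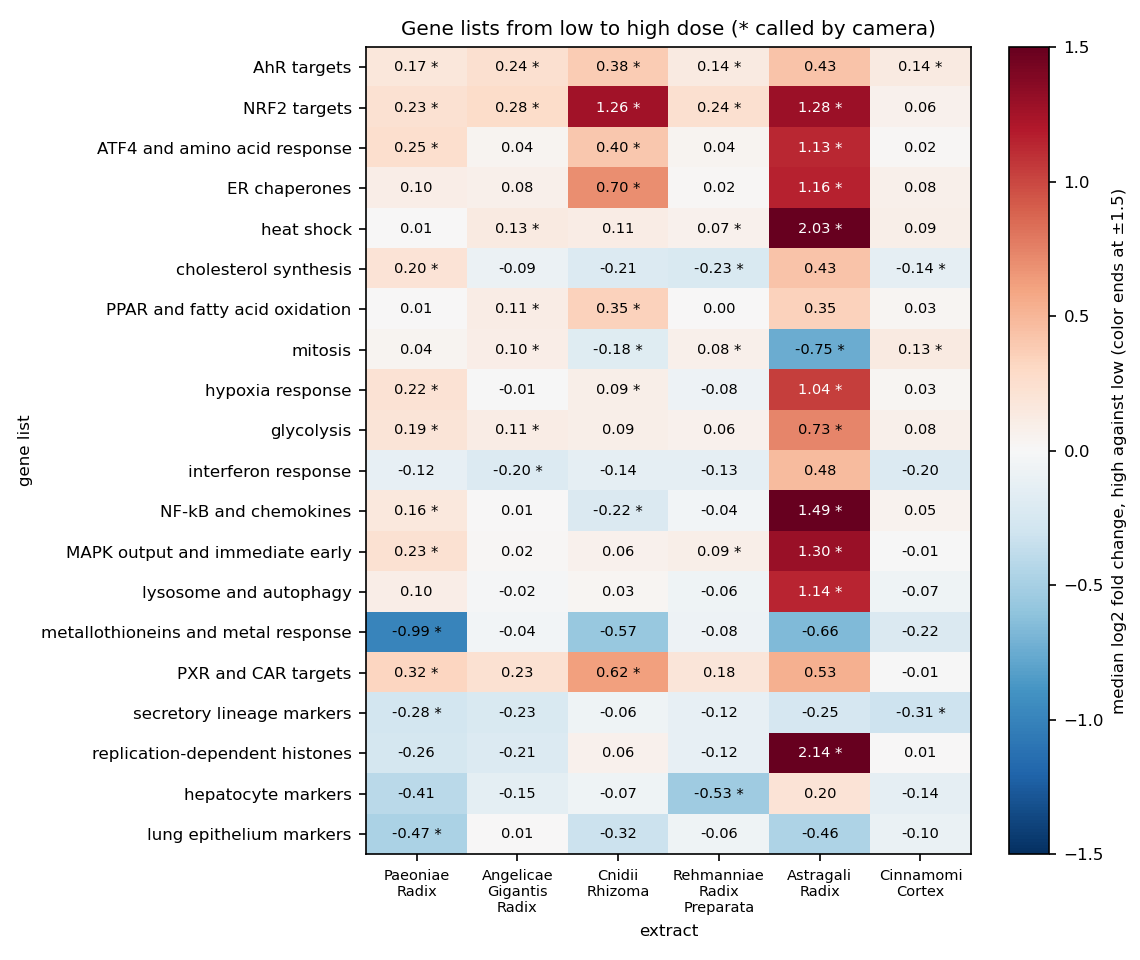
Median log2 change between the high and low dose for each gene list (vertical) and extract (horizontal) as a colour scale, with an asterisk where camera called the list. The NRF2 list is called for 5 of the 6 extracts, and heat shock has a median of 2.03 with Astragali Radix.

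Cnidii Rhizoma and Rehmanniae Radix Preparata at 500 µg/mL differed directly in 1575 genes, 864 higher with Cnidii Rhizoma and 711 lower (670 and 944 under library totals). AKR1C2 was higher by log2 4.28 ± 0.12 (adjusted p = 8.5e-28), HMOX1 by 2.18 ± 0.10, and FABP1 by 2.82, while CLIC5 was lower by -2.10 and CXCL8 by -0.77 ± 0.12. NRF2 targets had 27 of 28 higher (28 adjusted over the list alone, adjusted p = 3e-09), PPAR genes 13 of 18 (13 adjusted over the list alone, 1.1e-09), ER chaperones 17 of 18 (17 adjusted over the list alone, 6.5e-05) and ATF4 genes 18 of 26 (20 adjusted over the list alone, 3e-09). Mitosis had 3 of 26 lower (11 adjusted over the list alone, adjusted p = 1e-05). AhR targets (4 of 10 higher, 7e-06), PXR and CAR targets (6 of 9 higher, 0.0026), hypoxia (6 higher and 1 lower of 21, 0.0036) and NF-kB (4 of 20 lower, 0.0061) were also called. Adjusted over the list alone their counts were 4, 7 higher and 1 lower, 8 and 2, and 2 higher and 7 lower.

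Astragali Radix and Cinnamomi Cortex at 500 µg/mL differed in 11930 genes, 6158 higher with Astragali Radix and 5772 lower (4176 and 8189 under library totals). HSPA6 was higher by log2 12.67 ± 0.55 (11.36 without Astragali Radix high-dose library 3 for HSPA6, Astragali Radix high vs Cinnamomi Cortex high), HMOX1 by 5.17 ± 0.11, CDKN1A by 4.96 ± 0.10 and the histone H2BC5 by 2.42 ± 0.16, and MKI67 was lower by -2.26 ± 0.19 and MUC2 by -2.34 ± 0.16. The called lists were heat shock (17 of 18 higher), NRF2 (26 of 28, adjusted p = 0.025), ATF4 (23 of 26), ER chaperones (18 of 18, 0.043), hypoxia (15 of 21), NF-kB (16 of 20), MAPK (16 of 23), lysosome (20 of 22, 0.043), histones (12 of 12, 0.036) and mitosis (22 of 26 lower, 5.2e-05), with the same counts adjusted over the list alone. Without Astragali Radix high-dose library 2 ER chaperones (0.093), MAPK (0.074) and histones (0.054) were not called, and without library 1 lysosome was not (0.06).

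The low doses of the 6 extracts differed from the vehicle in more genes than from one another. Against vehicle, MAMDC4, a membrane protein gene, was higher over the 17 low-dose libraries (7.77 ± 0.923 against 3.46 ± 0.349 CPM, log2 1.10 ± 0.13, adjusted p = 1.9e-07). So was PGGHG, a collagen glucosidase (122 ± 9.61 against 60 ± 2.69). CD55, which protects cells from complement, was lower (52.1 ± 2.52 against 76.4 ± 11.3, -0.61 ± 0.10). The mitochondrial MT-CO1, of cytochrome oxidase, was at 16300 ± 1360 against 21400 ± 2570 CPM (-0.46 ± 0.15, adjusted p = 0.037), called over the pooled low doses but in none of the 6 taken singly, whereas the 3 genes before it were called in all 6. The AhR-induced CYP1A1 was lower by -2.23 ± 0.29, but the vehicle libraries stood at 5.93, 0.784 and 1.3 CPM. Between the low doses of any 2 extracts edgeR called 0 or 1 gene, or 0 to 12 in the fit without the Astragali Radix high-dose libraries. Between the pooled low doses of code sets 11 and 13 it called 0 (331 at an unadjusted p under 0.05, and 0 by DESeq2). In all 6 low doses 135 genes were higher and 61 lower. The split depended on the processing, at 348 and 27 under library totals, 119 and 122 with GC offsets, 229 and 123 with the Wald test of DESeq2 and 968 and 901 without the Astragali Radix high-dose libraries. In comparison, 8 simulations of unchanged groups against the same vehicle gave 0 at most. They called at most 1 gene in any single comparison, so 0 in all 6 was nearly certain in advance and decides nothing. Independent lists would give 1.7e-06, but the 6 comparisons share the vehicle libraries and are not independent. The median correlation of fold changes across genes between extracts was 0.634 (0.508 simulated) and the covariance 0.14 (0.0795 simulated). Much of the correlation thus arose in simulation from the shared vehicle alone. With 3 vehicle libraries the vehicle could not be split. Mitochondrial transcripts took 9.2% of counts in vehicle on average and 6.6 to 7.233% in the low-dose groups, and the 10 highest genes 10.83% and 8.567 to 9.067%. Single libraries overlapped, with mitochondrial shares of 8% in vehicle library 1 and 8.6% in Cinnamomi Cortex low-dose library 1. Of the 196 genes, 84 were still called alike in all 6 without vehicle library 2, 53 without library 3 and 93 with no filter.

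At the low dose against vehicle, 543 genes were higher and 274 lower with Paeoniae Radix, 240 and 101 with Angelicae Gigantis Radix, 335 and 190 with Cnidii Rhizoma, 497 and 278 with Rehmanniae Radix Preparata, 378 and 196 with Astragali Radix and 298 and 145 with Cinnamomi Cortex. Under library totals the splits were 1056 and 138, 623 and 56, 786 and 115, 1100 and 141, 936 and 108, and 689 and 71, in that order. CYP1B1, an estrogen and xenobiotic hydroxylase, and TIPARP, a feedback repressor of AhR, were lower at the low dose of Paeoniae Radix (log2 -0.63 ± 0.10 and -0.37). The vehicle varied in CYP1B1 (65 ± 20.9 CPM, against 43.3 ± 1.7 at the low dose), and CYP1A1 was lower at the low dose of all 6 extracts. A difference of the vehicle libraries therefore cannot be told apart from an effect of Paeoniae Radix. For TIPARP, Paeoniae Radix low vs vehicle, the call was lost without vehicle library 1 (adjusted p = 0.058) or low-dose library 1 (0.052), and for CYP1A1, Paeoniae Radix low vs vehicle, without vehicle library 1 (0.19). AhR targets had 3 of 10 lower (3 adjusted over the list alone, adjusted p = 0.022, but 0.055 without the Astragali Radix high-dose libraries). For the other 5 extracts camera called no list at the low dose with an estimated correlation, and 2 to 10 with the preset one. The totals moved with single libraries. Paeoniae Radix had 817, or 342 and 200 without vehicle libraries 2 and 3 and 407, 529 and 212 without its own 1, 2 and 3. Angelicae Gigantis Radix had 341, or 140 and 116 without those vehicle libraries and 25 and 30 without its own 2 and 3. Cnidii Rhizoma had 525, or 245 and 171, and 260, 312 and 200 without its own 1, 2 and 3. Rehmanniae Radix Preparata had 775, or 377 and 222, and 418, 231 and 481. Astragali Radix had 574, or 264 and 182, and 285 and 180 without its own 2 and 3, and Cinnamomi Cortex 443, or 201 and 193, and 120 and 154.

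At the medium dose against vehicle, 353 genes were higher and 181 lower with Paeoniae Radix, 173 and 122 with Angelicae Gigantis Radix, 748 and 514 with Cnidii Rhizoma, 196 and 70 with Rehmanniae Radix Preparata and 502 and 294 with Cinnamomi Cortex. Under library totals the splits were 886 and 120, 424 and 79, 1100 and 379, 324 and 48, and 1139 and 150, in that order. The low doses already differed from the same vehicle, and no medium dose was tested against its low dose. In these counts a difference of the vehicle libraries therefore cannot be told apart from an effect of the medium dose. Paeoniae Radix had 3 of 10 AhR targets lower (1 higher and 3 lower adjusted over the list alone, adjusted p = 0.045) and 2 of 26 ATF4 genes higher (5 adjusted over the list alone, adjusted p = 0.042), both at 0.05 without the Astragali Radix high-dose libraries, with CYP1B1 by log2 -0.67 ± 0.10. CYP1B1 varied between the vehicle libraries (65 ± 20.9 CPM), and the other 2 AhR members were less stable. For CYP1A1, Paeoniae Radix medium vs vehicle, the call was lost without vehicle library 1 (0.053) and with the Wald test of DESeq2. For TIPARP, Paeoniae Radix medium vs vehicle, it was lost under library totals. It was also lost without vehicle library 1 (0.14) or 3 (0.078) or its own library 1 (0.065), 2 (0.07) or 3 (0.11). Rehmanniae Radix Preparata had 1 of 15 Wnt markers lower (4 adjusted over the list alone, median -0.21, adjusted p = 0.028, but 0.052 without those libraries). For Angelicae Gigantis Radix and Cinnamomi Cortex camera called 0 lists with an estimated correlation, and 4 and 6 with the preset one. The total for Paeoniae Radix was 534, or 241 and 178 without vehicle libraries 2 and 3 and 279 and 152 without its own 1 and 3. Angelicae Gigantis Radix had 295, or 126 and 90 without those vehicle libraries and 11 and 24 without its own 2 and 3. Cnidii Rhizoma had 1262, or 742 and 474, and 716, 604 and 696 without its own 1, 2 and 3. Rehmanniae Radix Preparata had 266, or 144 and 141, and 117 and 170 without its own 1 and 2, and Cinnamomi Cortex 796, or 375 and 260, and 301 and 274 without its own 2 and 3.

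No call was made in any of the 26 comparisons for 10 of the 31 lists. Those nearest the threshold were FOXO targets, which respond to inhibition of PI3K (20 genes, lowest adjusted p = 0.052, Rehmanniae Radix Preparata high against vehicle), enterocyte markers (17 genes, 0.056, Cnidii Rhizoma against Rehmanniae Radix Preparata), p53 targets (17 genes, 0.069, Paeoniae Radix high against vehicle) and fatty acid synthesis (11 genes, 0.078, Cinnamomi Cortex high against low). The others were S phase genes (24, 0.12), mitochondrial genome transcripts (13, 0.25), FXR targets (7, 0.26), fibroblast markers (3, 0.29), leukocyte markers (7, 0.44) and cytosolic ribosomal proteins (71, 0.54).

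The changes from low to high dose were weakly alike across extracts. Over 15 pairs of extracts the Pearson correlation across 17089 genes had a median of 0.127 (0.055 to 0.207), and over the 9376 genes at 10 CPM or more a median of 0.309 (0.081 to 0.508), where genes are not independent replicates. Paeoniae Radix and Cnidii Rhizoma shared 62 genes higher and 65 lower, where independent lists would share 7.9 and 7.6. Another 21 were higher with Paeoniae Radix and lower with Cnidii Rhizoma, and 4 the reverse. Cnidii Rhizoma and Astragali Radix shared 607 higher and 502 lower, against 333.2 and 280 for independent lists. In opposite directions, 163 were higher with the first and lower with the second and 197 the reverse. All 9 genes higher with Angelicae Gigantis Radix, AKR1B10 and NQO1 among them, were also higher with Cnidii Rhizoma, against 0.5 for independent lists. These comparisons shared no libraries.

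Samul-tang, whose 4 plants were all measured singly (Angelicae Gigantis Radix, Cnidii Rhizoma, Paeoniae Radix and Rehmanniae Radix Preparata), and Sagunja-tang, which holds none of them, had 1 library per dose, so their differences have no replicate check and no test. In the Samul-tang libraries AKR1C2 was at 52, 15.7 and 12.7 CPM at the high, medium and low dose (11.5 ± 1.74 in vehicle), and SLC38A4 at 12.1, 3.7 and 2.8 (2.63 ± 0.194 in vehicle). HMOX1 and NQO1, given whatever their result, were at 25.1, 13.5 and 11.1 CPM and at 864, 584 and 533. FAXDC2 was at 4.9 CPM at the high dose and 11.3 ± 0.0946 in vehicle. In the Sagunja-tang libraries ABCG1 was at 7.22, 4.49 and 3.73 CPM (3.27 ± 0.284 in vehicle), HMOX1 at 15.3, 11.1 and 12.3 and NQO1 at 659, 551 and 531. The urea transporter SLC14A1 differed by log2 -1.07 between high and low dose. Among the genes picked by their difference from vehicle at the Samul-tang high dose, the largest were RN7SL2, a signal recognition particle RNA (log2 2.64), and the initiation factor gene EIF3CL (-2.81), both with near-identical copies.

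The gene sets that rose or fell with a single plant were set beside the formulas, as medians of log2 high minus low. With Samul-tang the 922 genes higher with Cnidii Rhizoma had a median of 0.163 (0.421 with the plant itself), and its lower genes one of -0.238 (-0.452). The corresponding medians were 0.126 (0.384) and -0.308 (-0.614) for Paeoniae Radix, 0.614 (0.53) and -0.411 (-0.422) for Rehmanniae Radix Preparata and 1.241 (0.583) for the 9 genes higher with Angelicae Gigantis Radix. With Sagunja-tang they were 0.086 and -0.122 for Cnidii Rhizoma, 0.111 and -0.252 for Paeoniae Radix, 0.346 and -0.325 for Rehmanniae Radix Preparata and 0.423 for Angelicae Gigantis Radix. All 9 genes higher with Angelicae Gigantis Radix were also called higher with Cnidii Rhizoma. So were 8 of the 10 higher with Rehmanniae Radix Preparata. The medians of these sets therefore cannot be assigned to a single plant. NRF2 targets had a median of 0.638 with Samul-tang and 0.339 with Sagunja-tang. The Cnidii Rhizoma set higher with Samul-tang lay at percentile 100 of 10000 random sets matched on level, which describes these libraries alone. The 8 genes higher with Cinnamomi Cortex, which is not one of the 4 plants of Samul-tang, had a median of 0.27 with Samul-tang and 0.22 with Sagunja-tang. At 10 CPM or more 12 genes differed by log2 1 or more between the doses of Samul-tang and 1 with Sagunja-tang.

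**Figure D4:**
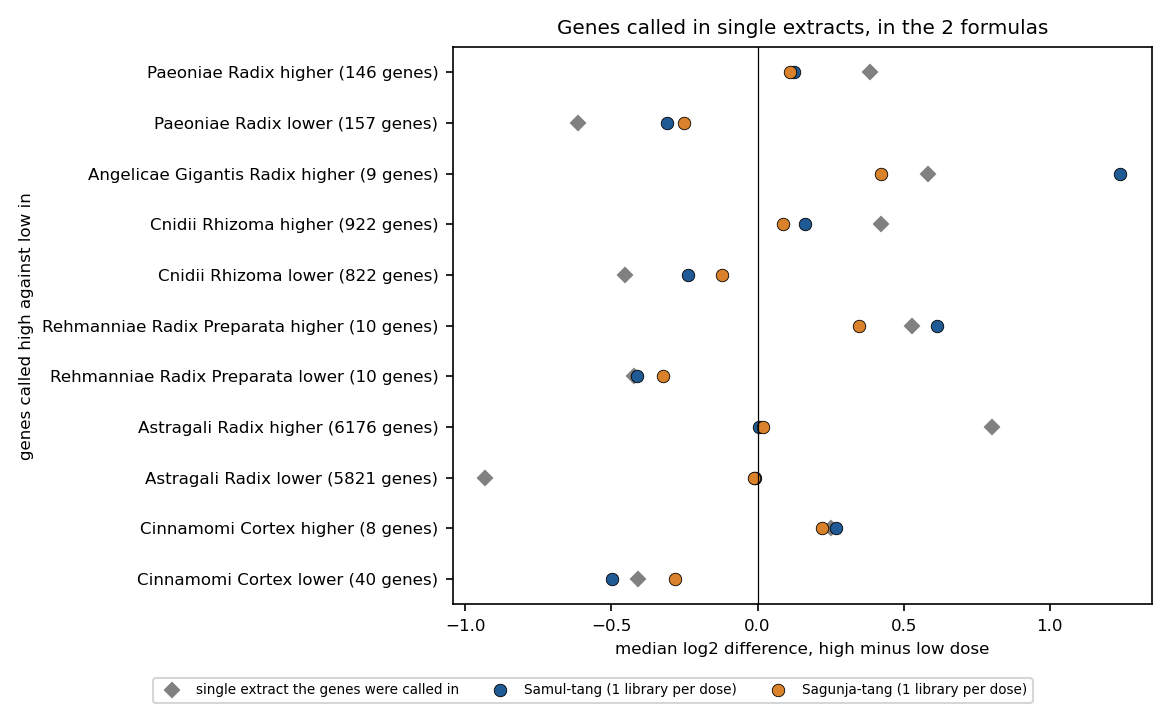
Median log2 difference between the high and low dose library of Samul-tang and Sagunja-tang for the gene sets called higher or lower with each single plant. For genes higher with Angelicae Gigantis Radix the median is 1.241 with Samul-tang and 0.423 with Sagunja-tang. All 9 of these genes were also called higher with Cnidii Rhizoma.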

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

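The tests of degraded libraries and of separate handling of the vehicle were set before their results were seen, and the tests of GC content, dose, exchanged labels, paralogs, solvent and other splits only after.

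The change from the low to the high dose differed between extracts of one code set, by a test of the difference itself. Between Cnidii Rhizoma and Rehmanniae Radix Preparata 610 genes differed in this way. The signed log2 change was higher for Cnidii Rhizoma in 363 and lower in 247, which can include genes that fell more with Cnidii Rhizoma. Among genes chosen after their values were seen, AKR1C2 differed by log2 4.05 ± 0.17 SE (edgeR, adjusted p = 2.6e-21), the exporter ABCG1 by -1.13 ± 0.16 (adjusted p = 4.1e-06) and TXNIP by 0.42 ± 0.10. Between Astragali Radix and Cinnamomi Cortex 10085 genes differed, 5150 and 4935 by direction, with HMOX1 by 5.22 ± 0.15, CDKN1A by 4.98 ± 0.13 and MKI67 by -2.19 ± 0.25. That count and these SE come from the fit of all groups, which understates the spread of the Astragali Radix high-dose libraries. The difference was not tested in a fit of these groups alone.

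The high dose of Astragali Radix lay far from every other group, with 11997 genes changed against its own low dose. Libraries that failed or degraded at this dose alone should leave the lower dose with no related change, but of 950 genes called between the medium doses of Astragali Radix and Cinnamomi Cortex (234 higher and 716 lower) 89.9% had the same direction between the high doses, against 65.9% of all genes. This argues against failed libraries as the whole cause, while a loss of RNA quality in dying cells was not tested. An exchange of the Astragali Radix and Cinnamomi Cortex labels cannot be told apart from a true difference, because 0 other groups carry either extract. A toxic response of the cells to the extract stays open as a hypothesis.

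The low doses of all 6 extracts differed from the vehicle alike, in 135 genes higher and 61 lower (348 and 27 under library totals, 119 and 122 with GC offsets, 229 and 123 with the Wald test of DESeq2, and 968 and 901 without the Astragali Radix high-dose libraries). GC content as the whole cause is argued against, since 82% of these genes (159 of 194) were still called alike with GC offsets. An effect that grows with dose is argued against too. For each extract, genes called alike in the low doses of the other 5 (199 to 252 genes) had a median change from its low to its high dose, signed by that direction, of -0.37 to 0.004, with upper quartiles of 0.027 to 0.168. The vehicle libraries were also higher on average in mitochondrial transcripts, at 9.2% of counts against 6.6 to 7.233% in the low-dose groups. So was the share of the 10 highest genes (10.83% against 8.567 to 9.067%). Single libraries overlapped, however. Vehicle library 1 had 8% and 9.8%, and Cinnamomi Cortex low-dose library 1 had 8.6% and 10.3%. Separate handling of the vehicle libraries, which have a code set of their own although the labels place all 60 libraries in the same batch, may be the source and cannot be told apart from the treatment, because no extract library shares that code set and the 0 genes called between 2 other code sets do not speak to the vehicle. An effect common to all extracts or their solvent that is already full at the low dose was not tested and stays open.

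Reductase genes of the NRF2 list were higher at the high dose of several extracts, with AKR1B10 called in all 6 against the low dose (log2 0.62 with Paeoniae Radix, 0.87 with Angelicae Gigantis Radix, 2.95 with Cnidii Rhizoma, 0.56 with Rehmanniae Radix Preparata, 1.24 with Astragali Radix and 0.39 with Cinnamomi Cortex). The 14 members without a near-identical copy had a median over the 6 extracts of 0.27. With Cnidii Rhizoma and Astragali Radix all 14 were higher (median log2 1.21 and 1.26). For the rise of the list with these extracts, this argues against reads shared among AKR1C paralogs as the whole cause. With the other extracts the medians were only 0.13 to 0.29, with 0 to 4 of the 14 called. Other genes cannot show how reads were divided among the AKR1C genes themselves. More solvent at the high dose may contribute and cannot be told apart from the extract, because the labels give no solvent per dose, and AKR1B10 was above vehicle by a median of 0.75. Activation of NRF2 by constituents of the extracts is a hypothesis that these data do not test.

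With 3 libraries against 3 there are 10 splits, so the share of splits with as many genes cannot fall under 0.05, and in each of 22 comparisons fitted on its 2 groups the real split was the 1 with the most genes. The real totals and the highest of the other splits for high, medium and low dose against vehicle and for high against low were 2811 and 0, 1924 and 0, 2702 and 3, and 911 and 2 for Paeoniae Radix. They were 5337 and 0, 3896 and 1, 2254 and 0, and 3616 and 0 for Cnidii Rhizoma, and 2559 and 0, 951 and 2, 2718 and 1, and 174 and 4 for Rehmanniae Radix Preparata. For Astragali Radix they were 6281, 4932, 2193 and 6113, each with 0, and for Cinnamomi Cortex 3391 and 0, 3011 and 2, 851 and 0, and 373 and 1. Cnidii Rhizoma against Rehmanniae Radix Preparata gave 3614 and 0 and Astragali Radix against Cinnamomi Cortex 6167 and 0.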

How the results depend on the processing

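Library totals, GC offsets and the fit without the Astragali Radix high-dose libraries were chosen after seeing the data, and the other alternatives were planned. Over the 26 counts of changed genes, DESeq2 size factors and GC offsets moved none by more than 1.5 times. No named gene reversed under these or under DESeq2's Wald test, no filter, library totals, the block or a fit of 2 groups. The test kept 679 of 680 named calls with DESeq2 size factors, 662 of 672 with the Wald test, 664 of 680 with GC offsets, 659 of 680 with library totals, 628 of 680 with no filter and 660 of 678 in fits of 2 groups. It kept 486 of 486 without the Astragali Radix high-dose libraries and 186 of 230 with low doses as reference. Leaving out libraries one at a time kept 490 of 681. Of 121 list calls, 121 were kept with DESeq2 size factors, 117 with no filter and 121 with the preset correlation. The preset correlation called more lists in every comparison (19 against 11 for Paeoniae Radix high against vehicle), so that it kept all was nearly certain. Without the Astragali Radix high-dose libraries 72 of 90 were kept and 18 lost, not all of them named above. Leaving out libraries one at a time kept 78 of 108 list calls. At the depths here a 1.5-fold change was recovered in 78% of simulated genes for Cnidii Rhizoma high against vehicle, where all groups varied alike by construction. Where a group was left with 1 library, it was assumed to vary like the others. The cause of the differences below was not tested.

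CYP1A1 reversed. Its log2 change was -1.91 with Paeoniae Radix high and -1.12 with Cnidii Rhizoma high against vehicle, and 0.33 and 1.2 against the other low doses. For CYP1A1, Cnidii Rhizoma high vs vehicle, the change ran from -1.56 without vehicle library 2 to 0.2 without vehicle library 1.

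Without the Astragali Radix high-dose libraries the counts for high, medium and low dose against vehicle and high against low were 4456, 3568, 4298 and 1589 for Paeoniae Radix and 3355, 3198, 3375 and 191 for Angelicae Gigantis Radix. They were 6340, 4595, 3522 and 3905 for Cnidii Rhizoma, 3700, 2785, 3954 and 242 for Rehmanniae Radix Preparata, and 4324, 4146, 3185 and 964 for Cinnamomi Cortex. Astragali Radix had 5751 and 3709 at medium and low dose, and Cnidii Rhizoma against Rehmanniae Radix Preparata 3727.

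With only the 2 groups in the fit the counts were 2811, 1924, 2702 and 911 for Paeoniae Radix and 1543, 1525, 1786 and 145 for Angelicae Gigantis Radix. They were 5337, 3896, 2254 and 3616 for Cnidii Rhizoma, 2559, 951, 2718 and 174 for Rehmanniae Radix Preparata, 6281, 4932, 2193 and 6113 for Astragali Radix and 3391, 3011, 851 and 373 for Cinnamomi Cortex, with 3614 and 6167 between extracts.

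The Wald test of DESeq2 gave 916 and 1265 for Paeoniae Radix medium and low, 808, 682, 683 and 32 for Angelicae Gigantis Radix, 959 for Cnidii Rhizoma low, 1055, 470, 1201 and 53 for Rehmanniae Radix Preparata, 1017 for Astragali Radix low and 1552, 1240, 793 and 132 for Cinnamomi Cortex. Library totals gave 1006 for Paeoniae Radix medium, 692, 503 and 679 for Angelicae Gigantis Radix, 901 for Cnidii Rhizoma low, 1241 for Rehmanniae Radix Preparata low, 1044 for Astragali Radix low and 1289 and 760 for Cinnamomi Cortex medium and low. No filter gave 493, 520 and 37 for Angelicae Gigantis Radix medium, low and high against low, and 46 and 91 for Rehmanniae Radix Preparata and Cinnamomi Cortex high against low. The mean of the other 5 low doses as reference gave 690 for Paeoniae Radix high, 25 for Angelicae Gigantis Radix, 90 for Rehmanniae Radix Preparata and 81 for Cinnamomi Cortex.

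With the replicate number as a block, Rehmanniae Radix Preparata high against low had 33 genes in place of 20, and no other count moved by over 1.5 times. It kept 674 of 680 named calls and 119 of 121 list calls, the hepatocyte list with Rehmanniae Radix Preparata (adjusted p = 0.05, high against low) and ER chaperones with Astragali Radix (0.05, against vehicle) being lost. Whether the numbers pair the libraries was not settled. Over 171 pairs of groups same-numbered libraries correlated at 0.032 on average (0.067 within a code set) and others at -0.015, and in 15 pairs of groups every same-numbered correlation was over 0.1. Among the high and low doses of one extract these were Paeoniae Radix (lowest 0.129), Rehmanniae Radix Preparata (0.176) and Cinnamomi Cortex (0.209), while with the vehicle the lowest was -0.394. As a hint from the data and not the design, 38 of 54 libraries correlated best with their own number.

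Leaving out 1 library at a time, the counts ran for high, medium and low dose against vehicle and high against low from 490 to 1210, 152 to 587, 200 to 796 and 113 to 202 for Paeoniae Radix, and from 77 to 486, 11 to 415, 25 to 442 and 1 to 3 for Angelicae Gigantis Radix. They ran from 278 to 666, 117 to 261, 222 to 777 and 6 to 10 for Rehmanniae Radix Preparata, and from 306 to 1065, 260 to 861, 120 to 599 and 8 to 22 for Cinnamomi Cortex. Cnidii Rhizoma medium ran from 474 to 1251 and low from 171 to 589, and Astragali Radix medium from 1153 to 2182 and low from 180 to 593.

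The median correlation across extracts was 0.309 at 10 CPM or more and 0.044 for high against medium dose. For high dose minus vehicle the medians with Samul-tang were -0.351 for genes lower with Paeoniae Radix, 1.338 for those higher with Angelicae Gigantis Radix, 0.183 for those higher with Cnidii Rhizoma and 0.735 and -0.345 for those higher and lower with Rehmanniae Radix Preparata, and with Sagunja-tang 0.065 and -0.232 for Paeoniae Radix, 0.719 for Angelicae Gigantis Radix and 0.098 for genes higher with Cnidii Rhizoma. For medium minus low dose those of Samul-tang were 0.042 and -0.078 for Paeoniae Radix, 0.239 for Angelicae Gigantis Radix, 0.039 and -0.041 for Cnidii Rhizoma and 0.126 and -0.094 for Rehmanniae Radix Preparata, and those of Sagunja-tang 0.015 and -0.035, 0.077, 0.011 and -0.015, and 0.059 and -0.069.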

Other observations

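Gene lists in the formula libraries were read after the values were seen and have no replicate check. Cholesterol synthesis genes had a median log2 high minus low of -0.208 with Samul-tang and -0.159 with Sagunja-tang, and the antiviral interferon response genes one of -0.321 and -0.259. All 4 medians lay at percentile 0 of 10000 random sets matched on level. HMGCS1, an early enzyme of cholesterol synthesis, was at 241, 302 and 315 CPM at the high, medium and low dose of Samul-tang and at 239, 292 and 312 with Sagunja-tang, with 277 in vehicle. Secretory lineage markers had medians of -0.216 and -0.273. In Samul-tang the fatty acid binding gene FABP1 was at 4.42, 2.18 and 1.8 CPM and ABCG1 at 7.09, 4.32 and 4.1.

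Across the single extracts, chosen after the values were seen, the stress cytokine GDF15 rose against the low dose by log2 2.42 ± 0.05 SE with Astragali Radix, 0.49 ± 0.05 with Paeoniae Radix, 0.40 ± 0.05 with Cnidii Rhizoma and 0.25 ± 0.05 with Rehmanniae Radix Preparata (edgeR, adjusted p = 0.0057), and had values of -0.02 with Angelicae Gigantis Radix and -0.11 with Cinnamomi Cortex that were not called. The increase with Rehmanniae Radix Preparata was not called without its low-dose library 1 or 2 or its high-dose library 3, with no filter or with GC offsets. NQO1 was called with 5 extracts and stood at 0.14 with Cinnamomi Cortex (adjusted p = 0.2). Of 14 NRF2 targets without a near-identical copy, 14 were higher with Cnidii Rhizoma and 14 with Astragali Radix, 4 with Paeoniae Radix, 1 each with Angelicae Gigantis Radix and Rehmanniae Radix Preparata and 0 with Cinnamomi Cortex by edgeR.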
